A study of Mus musculus with 20 samples.

How the data were processed

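The deposited table of counts held 1 column of raw counts for each of the 20 libraries and no normalization, and its unfiltered state was checked on the values (8790 of 32245 gene symbols were 0 in every library). Per the labels, ribosomes of mouse hippocampus carrying the HA tag on RPL22 were pulled down with an anti-HA antibody and the libraries were made with a stranded kit that selects poly-adenylated RNA. Per the submitters' processing notes, the tools were STAR 2.7.5b, featureCounts and SAMtools 1.10 and the genome build was mm10. The annotation, the strand setting, the version of featureCounts and the treatment of reads that map to several places are not given in the sources used here. Genes that share reads with a near-identical copy, such as hemoglobin and ribosomal protein genes, and genes that overlap others are therefore uncertain. Of the symbols, 31424 (97.5%) were found in GENCODE release vM21 of the mm10 assembly, from which coordinates were taken.

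Ages and batches were taken from the labels. The P5 libraries carry a series name as well as a replicate number, and replicates 1 to 3 of the first series belong to batch A while replicates 1 and 3 of the second belong to batch B. No pair of libraries of an age agreed within sampling noise (chi-square per degree of freedom 3.85 to 43.5). None was therefore treated as a repeat sequencing of another, and each was used as 1 sample. The test cannot show separate animals, since preparations of the same lysate can also differ by more than sampling noise. The labels leave open whether P5 libraries of the same number in different series share an animal or lysate. The values of these pairs (43.5 for number 1, 29.3 for number 3) also carry the batch difference. Total counts ranged from 15.9 to 20.7 M at P5, 21.8 to 24.9 at P7, 16.7 to 16.8 at P10, 18.7 to 19.4 at P15, 17.1 to 19.7 at P21 and 17.5 to 19.1 at P28. Levels below 0.12 to 0.189 CPM, which correspond to 3 counts, cannot be told from 0, and this floor covers counting error only.

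Counts were tested with edgeR 4.0.16 in R 4.3.3, with trimmed-mean (TMM) factors, the default filter on low counts by age (15373 genes left), robust quasi-likelihood fits and Benjamini-Hochberg adjustment with a threshold of 0.05. The model held a mean for each of the 6 ages and a term for batch B against batch A, which P5 alone makes estimable, and left 13 residual degrees of freedom. Because of this term, changes from P5 to P10, P15 or later rest in effect on the P5 libraries of batch A and the change from P5 to P7 on those of batch B, while mean CPM values at P5 are over all 5. The biological coefficient of variation was 8.46%. A log2 change is the fitted change of the later age against the earlier one, its SE is the change divided by the root of its F statistic, and CPM values are counts relative to the library total after TMM scaling. Neighboring ages were compared, as well as P15 and P28 with P5.

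Gene lists for 31 groups (pathways, receptor and channel families and markers of other cell types), the tests and the rule for named genes were fixed before the data were examined. The lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the 31 lists of a comparison, and again with an estimated correlation and with fry. Named genes are the 10 highest and 10 lowest fold changes for P15 and P28 against P5 and the 6 highest and 6 lowest for each step, among genes past the threshold with a mean of at least 5 CPM in 1 of the ages and no overlap between the libraries of the 2 ages, without predicted, pseudogene or sex-linked names. A further part of the rule takes the 4 members of each list with the smallest p, every member past the threshold where these are 6 or fewer, and a fixed panel of genes of synapses, maturation and other cell types. Members that moved against their list, as well as Trp53bp1, Bcar1 and the genes set beside them, fall outside that rule and were chosen after their values were seen. Results for some genes under the rule are not reported.

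The test was run on simulated counts drawn from the mean of each gene over all samples, its dispersion and the library sizes, with changes planted in 1 age. Genes were drawn independently and without a difference between batches. Far fewer were changed than the real data gave from P5 to P7 or P15. The rates that follow hold for these settings and do not measure the accuracy of the real calls. For P15 against P5 (15090 genes), 74% of genes changed 2-fold and 59.2% of those changed 1.5-fold were recovered, and 7.5% of the calls were unchanged genes; for P28 against P21 (15081 genes) these were 76.3%, 69.7% and 4.14%, and for P7 against P5 (15084 genes) 82.5%, 55.1% and 7.5%. Alternatives were DESeq2 size factors, total counts in place of TMM factors, no filter and a stricter filter, DESeq2 1.42.0, limma-voom, no batch term, the replicate number as a block, the P5 libraries of batch B left out or summed with those of the same number, the libraries of 1 batch or of 2 ages alone, other thresholds and each library left out in turn. Protein sequences were compared with the HA tag using Biopython 1.88 in Python 3.11.15, and figures were drawn with matplotlib 3.10.9.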

Results

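Ribosome-associated mRNA of hippocampal granule cells was measured at 6 postnatal ages in mice that carried Rbp4-Cre and the RiboTag allele. In RiboTag mice Cre recombination adds an HA epitope to RPL22, a protein of the large ribosomal subunit, so that ribosomes of Cre-expressing cells can be pulled from a tissue lysate with anti-HA antibody. What was sequenced is the poly-adenylated RNA that came down with those ribosomes, and no library of unselected hippocampal RNA was analysed here. The 20 libraries comprised 5 from postnatal day 5 (P5) and 3 each from P7, P10, P15, P21 and P28. They were prepared in 3 batches, named A, B and C here. Batch A held 3 P5 libraries and all those of P10 and P15, batch B held 2 P5 libraries and all those of P7, and batch C held those of P21 and P28. Total counts per library lay between 15.9 and 24.9 M, at which 3 counts equal 0.12 to 0.189 counts per M (CPM). The labels do not say that the libraries of an age came from separate animals, so the p-values measure only the spread between these samples.

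The course of expression over the 6 ages was the question the series addresses. The libraries lay in the order of age along the first principal component, which held 67.1% of the variance. Its mean was -71.9 ± 6.8 (SD, n = 5) at P5, -49.2 ± 9.7 (n = 3) at P7, 12.9 ± 4.8 at P10, 28.3 ± 3.1 at P15, 60.0 ± 3.4 at P21 and 67.7 ± 1.9 at P28. Of the 15373 genes tested, 12254 (79.7%) differed between ages. Among the 5310 of these whose fitted means spanned at least 2-fold, 1935 were highest at P5, 1332 at P7, 232 at P10, 287 at P15, 609 at P21 and 915 at P28. P21 and P28 cannot be told apart from batch C in any comparison with an earlier age. The P5 libraries of batch A had a mean of -76.8 on the first component and those of batch B -64.6, and 1548 genes differed between the 2 batches (1023 higher and 525 lower in B). Scaling by total counts gave 1697, of which 509 were higher and 1188 lower. The count of 1548 was 953 without P5 replicate 1 of batch A, 772 without P5 replicate 1 of batch B and 613 without P5 replicate 3 of batch B.

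**Figure D1:**
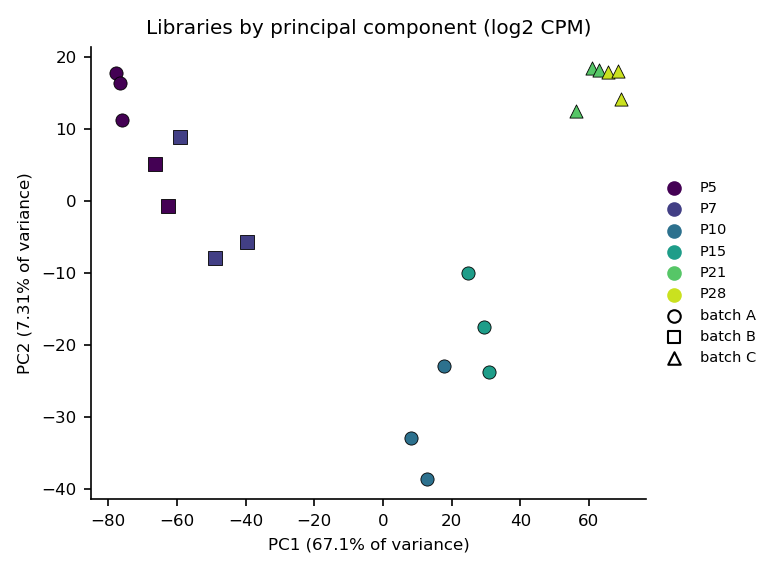
Each point is 1 of the 20 libraries, placed by the first component (x axis, 67.1% of variance) and the second (y axis, 7.31%) of log2 CPM. Color gives the age and shape the batch; the P5 libraries lie at the left (mean -71.9) and the P28 libraries at the right (mean 67.7).

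**Figure D2:**
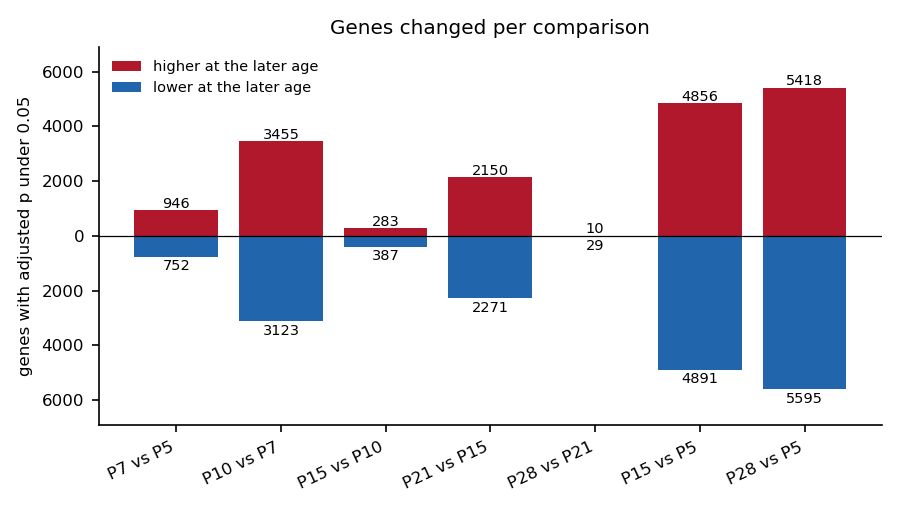
Bars give the number of genes with an adjusted p under 0.05 in each comparison, those higher at the later age above 0 and those lower below it. The count was 6578 from P7 to P10, which lie in different batches, and 39 from P21 to P28, both in batch C.

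Between P5 and P15, the longest span inside a single batch, immature neuron genes fell and postsynaptic density genes rose. Dcx, which encodes a microtubule-associated protein of migrating neurons, went from 739 ± 75.2 CPM (SD, n = 5) at P5 to 62.0 ± 2.79 (n = 3) at P15, a log2 change of -3.68 (SE 0.09, adjusted p = 2.4e-18). Slc30a3, whose product loads zinc into synaptic vesicles of mossy fibers, went from 45.9 ± 6.33 to 159 ± 1.69 CPM (log2 change 1.94, SE 0.07, adjusted p = 1.4e-16). The NMDA receptor subunit gene Grin2a went from 60.3 ± 11.7 to 347 ± 11.8 CPM (2.72, SE 0.12, adjusted p = 9.6e-13). Grin2b, the subunit gene that dominates at early ages, measured 748 ± 110 CPM at P5 and 688 ± 40.8 at P15, a difference within its error (0.02, SE 0.08, adjusted p = 0.84). Prox1, the transcription factor that marks granule cells, measured 547 ± 28.7 and 556 ± 12.4 CPM (0.02, SE 0.09, adjusted p = 0.84). Calb1 measured 603 ± 20.4 and 640 ± 34.6 CPM (adjusted p = 0.62). In the mm10 mouse assembly, GENCODE release vM21 places Dcx on chromosome X from 143855842 to 143933311, Slc30a3 on chromosome 5 from 31086106 to 31108237. Grin2a lies on chromosome 16 from 9567898 to 9995560 and Prox1 on chromosome 1 from 190118035 to 190170714. All 4 are on the minus strand and protein-coding.

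**Figure D3:**
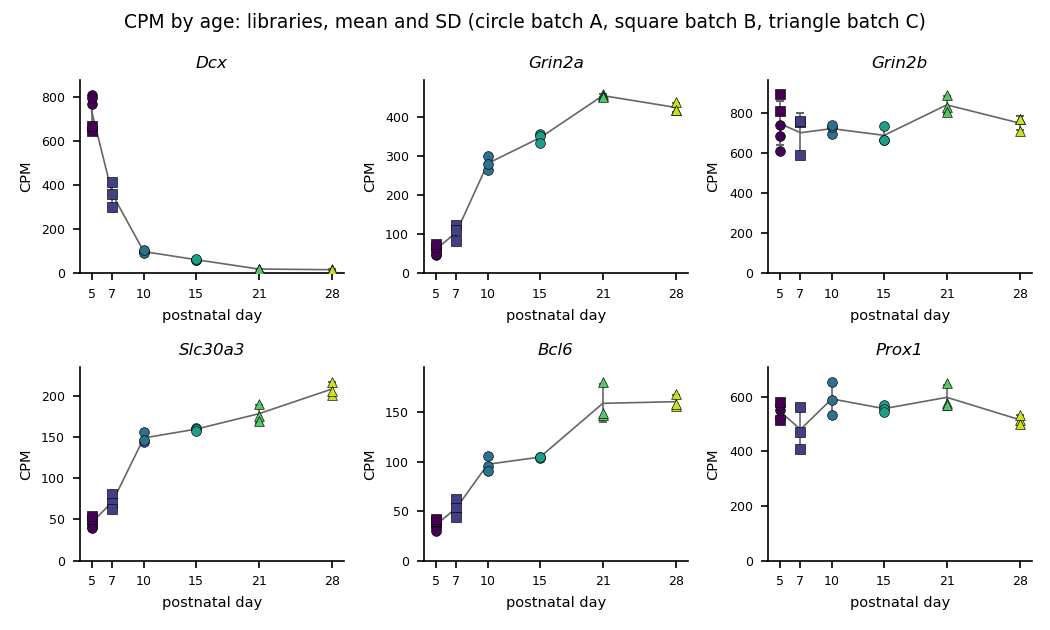
Points give the CPM of single libraries (y axis) against postnatal day (x axis) for Dcx, Grin2a, Grin2b, Slc30a3, Bcl6 and Prox1, shaped by batch; lines join the age means and bars give the SD. Dcx went from a mean of 739 CPM at P5 to 16.5 at P28 and Grin2a from 60.3 to 424, while Prox1 had means of 547 and 515.

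Of the 30 immature neuron genes tested, 24 fell and 4 rose from P5 to P15 (adjusted p = 2.1e-15 for the list). Besides Dcx, those with the smallest p were Crmp1, a mediator of semaphorin signals (log2 change -1.62, SE 0.06), the secreted guidance protein gene Draxin (-4.30, SE 0.16) and the transcription factor gene Neurod2, which rose (1.13, SE 0.07). The others that rose were Prdm8, Gpm6a and Dbn1, the last with a change of -0.93 under the spectrin covariate described below. Sox11, a factor of newborn neurons, fell by 1.86 (SE 0.10). Calb2 measured 24.2 ± 2.88 CPM at P5 and 12.7 ± 4.36 at P15 (adjusted p = 0.069). Of 75 axon guidance genes, 51 fell and 14 rose (adjusted p = 2.9e-09), among them the receptor genes Robo1 (-2.25, SE 0.09) and Nrp2 (-1.65, SE 0.07) and the semaphorin gene Sema4g (-2.14, SE 0.09). Cell cycle genes fell in 30 of 35 cases (adjusted p = 1.2e-06), with log2 changes of -2.65 (SE 0.23) for Top2a and -2.46 (SE 0.19) for Rrm2. Ccne1 (1.51, SE 0.12) and Mcm6 rose. Neural stem and progenitor genes fell in 17 of 20 cases (adjusted p = 3.3e-05), including the intermediate filament genes Nes (-2.72, SE 0.17) and Vim (-2.51, SE 0.11) and the radial glial gene Fabp7 (-3.79, SE 0.11). Hes1 and Lpar1 rose, Lpar1 with a change of -0.50 under that covariate. With an estimated correlation the immature neuron list (adjusted p = 0.0422) and the axon guidance list (adjusted p = 0.0433) stayed past the threshold. The cell cycle list (adjusted p = 0.187 with an estimated correlation) and the stem cell list (adjusted p = 0.19 with an estimated correlation) did not.

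Postsynaptic density genes rose in 38 of 44 cases from P5 to P15 and none fell (adjusted p = 4.0e-22, and 0.0433 with an estimated correlation). Camk2a, the kinase central to synaptic plasticity, reached 6350 ± 66 CPM from 2080 ± 410 (log2 change 1.83, SE 0.08). The calcineurin subunit gene Ppp3r1 (1.80, SE 0.07), the adhesion gene Icam5 (1.36, SE 0.06) and the scaffold gene Baiap2 (1.57, SE 0.07) rose with it. On the presynaptic side 45 of 63 genes rose and 10 fell (adjusted p = 6.1e-09, and adjusted p = 0.24 with an estimated correlation), among them Nptx1 (2.13, SE 0.08), Syt7 (from 183 ± 16.9 to 487 ± 13.8 CPM) and Vamp1 (2.29, SE 0.10). The vesicular glutamate transporter gene Slc17a7 rose by 1.44 (SE 0.07) while Slc17a6 fell by 1.05 (SE 0.21, adjusted p = 0.00049). Of 36 glutamate receptor genes 16 rose and 12 fell, with no shift of the list (adjusted p = 0.345). Grm2, a presynaptic metabotropic receptor gene, rose by 1.95 (SE 0.08), Cacng3, an AMPA receptor auxiliary subunit gene, by 1.69 (SE 0.08). Grin2d fell by 1.69 (SE 0.10). Of 21 genes of GABA-A receptors and chloride transport 11 rose and 5 fell (adjusted p = 0.002, and adjusted p = 0.323 with an estimated correlation). Gabrd rose by 2.01 (SE 0.10), Gabra4 by 1.37 (SE 0.06) and Slc12a5, the chloride exporter gene, by 1.05 (SE 0.06). Gabra3, Gabra5, Gabrg1, Gabrg3 and the chloride importer gene Slc12a2 fell. Gabra2 measured 57.8 ± 9.43 and 68.7 ± 3.13 CPM (adjusted p = 0.26).

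Granule cell identity genes rose in 14 of 18 cases from P5 to P15 and none fell (adjusted p = 2.6e-13, and adjusted p = 0.156 with an estimated correlation). Lct rose by 3.90 (SE 0.13) on the log2 scale, the cation channel gene Trpc6 by 2.85 (SE 0.12) and C1ql2 by 2.36 (SE 0.10), and the zinc transporter gene Slc30a3 was among them. Voltage-gated channel genes rose in 49 of 75 cases and fell in 17 (adjusted p = 2.8e-06, and adjusted p = 0.156 with an estimated correlation). The potassium channel genes Kcns2 and Kcnc4 rose by 1.62 (SE 0.08) and 1.24 (SE 0.06). Hcn3 fell by 2.26 (SE 0.11). Of 41 activity-regulated genes 30 rose (adjusted p = 5.6e-09, and adjusted p = 0.0546 with an estimated correlation), including Arl4d (2.96, SE 0.17), the granin gene Scg2 (1.27, SE 0.07) and Egr3 (0.98, SE 0.06). Fosl2, Nr4a3 and Sik1 fell. Among 108 synaptic adhesion genes 61 fell and 16 rose (adjusted p = 0.00137, and adjusted p = 0.429 with an estimated correlation). The members with the smallest p, Cntnap1 (3.18, SE 0.10), Gpr158 (1.75, SE 0.08) and Lrrc4 (1.12, SE 0.06), were among those that rose. Bcl6, a transcriptional repressor, rose by 1.69 (SE 0.10) from 35.7 ± 4.84 to 104 ± 0.598 CPM, and lies on chromosome 16 from 23965052 to 23988852.

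Nuclear respiratory chain genes rose and cholesterol biosynthesis genes fell between P5 and P15, though neither list call held with an estimated correlation. The nuclear genes of the respiratory chain rose in 72 of 80 cases and none fell (median log2 change 0.47, adjusted p = 1.0e-09, and adjusted p = 0.408 with an estimated correlation), among them Cox8a (1.14, SE 0.07), Ndufs7 (1.05, SE 0.07) and Ndufa1 (0.95, SE 0.07). Of 7 mitochondrially encoded genes 3 rose and 2 fell (median -0.27, adjusted p = 0.855). The others of the 13 such genes (mt-Co2, mt-Atp8, mt-Atp6, mt-Co3, mt-Nd3 and mt-Nd4l) did not pass the filter on low counts. Why they were so low was not examined, and the treatment of reads that map to several places is not known. Counts of this class are therefore uncertain in every comparison. Cholesterol biosynthesis genes fell in 23 of 26 cases (adjusted p = 1.2e-07, and adjusted p = 0.187 with an estimated correlation), including Cyp51 (-1.54, SE 0.08) and Nsdhl (-1.41, SE 0.11). Ebp, a sterol isomerase gene, rose. Cytosolic ribosomal protein genes fell in 53 of 82 cases by a small amount (median -0.22, adjusted p = 0.000274, and adjusted p = 0.603 with an estimated correlation), among them Rps12 (-0.64, SE 0.06) and Rpl22 itself (-0.34, SE 0.05). Rpl35a and Rpl7l1 rose. Many ribosomal protein genes have near-identical processed copies, so their counts are uncertain. Rbp4, whose regulatory region drives the Cre, measured 9.53 ± 0.856 CPM at P5 and 10.1 ± 2.53 at P15 (adjusted p = 0.66).

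The largest fold changes from P5 to P15 included those of 4 myelin genes. The rule for the highest and lowest fold changes required every library of the later age to lie on one side of every P5 library. That separation is therefore no further support for them. Among the 10 genes with the highest fold change, Mobp went from 0.19 ± 0.12 CPM at P5, about the level of 3 counts, to 159 ± 50.3 at P15, Mog from 0.0212 ± 0.0293 to 5.01 ± 1.71 and Mag and Mal from 0.616 ± 0.309 and 0.587 ± 0.236 to 21.1 ± 4.7 and 18.6 ± 6.8, all genes of myelin. Also among them were the cyclooxygenase gene Ptgs2 (log2 change 6.01, SE 0.27), the phospholipase gene Pla2g2f (5.58, SE 0.28), the troponin gene Tnnt2 (5.51, SE 0.33), the annexin gene Anxa11 (4.57, SE 0.15) and the actin-severing protein gene Gsn (4.75, SE 0.49). Those that fell most were the retinoic acid binding protein gene Crabp1 (-6.23, SE 0.23), Mgam (-5.36, SE 0.38), Cenpf (-4.95, SE 0.19), the receptor gene Pth2r (-4.59, SE 0.43), Trim67 (-4.57, SE 0.14), the collagen genes Col2a1 (-4.90, SE 0.39) and Col3a1 (-4.40, SE 0.41), the polysialyltransferase gene St8sia2 (-4.34, SE 0.19), Draxin (-4.30, SE 0.16) and Cd24a (-4.19, SE 0.35). Col3a1 stood at 213 to 298 CPM in the P5 libraries of batch A, to which its fitted change refers, and at 38.6 and 50.3 in those of batch B (-3.82 without the batch term). Cenpf, which encodes a kinetochore protein, stood at 4830 ± 323 CPM at P5, far above Mki67 (60.4 in batch A) and Top2a (15.4 ± 2.29).

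Markers of other cell types moved apart from one another between P5 and P15. Oligodendrocyte lineage genes rose in 15 of 20 cases (adjusted p = 2.2e-05, and adjusted p = 0.408 with an estimated correlation). Mbp, a main myelin protein gene on chromosome 18 from 82475146 to 82585637, rose by 3.49 (SE 0.22) and stood at 664, 821 and 1150 CPM in the 3 P15 libraries. The 4 members that fell were Pdgfra, Cspg4, Olig1 and Olig2. Endothelial and mural genes fell in 13 of 19 cases (adjusted p = 0.00868, and adjusted p = 0.408 with an estimated correlation), among them Cldn5 (-1.64, SE 0.17) and Cdh5 (-2.35, SE 0.26). Ly6c1, Slco1a4 and Egfl7 rose. Cajal-Retzius genes fell in 10 of 12 cases (adjusted p = 0.00519, and adjusted p = 0.24 with an estimated correlation), among them Reln (-2.26, SE 0.24) and Ebf2 (-2.71, SE 0.21). Car10 rose. Choroid plexus, ependymal and blood genes fell in 10 of 13 cases (adjusted p = 0.00616, and adjusted p = 0.365 with an estimated correlation), and Kl rose. Of 24 interneuron genes 9 rose and 9 fell (adjusted p = 0.855), with Gad1 higher by 0.90 (SE 0.09) and Lhx6 lower (-1.16, SE 0.15). Of 19 astrocyte genes 9 rose and 6 fell (median -0.02, mean 0.24, adjusted p = 0.927). Of 23 CA pyramidal genes 9 rose and 6 fell (adjusted p = 0.356). Of 14 mossy cell genes 5 rose and 4 fell (adjusted p = 0.443), and of 18 microglial genes 8 rose (adjusted p = 0.376). Aqp4 (32.2 ± 2.61 and 28.6 ± 3.89 CPM) and C1qa (3.10 ± 0.632 and 3.66 ± 1.19) did not pass the test. Fibcd1, a CA1 marker, rose by 0.80 (SE 0.22).

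In total 9747 genes (63.4%) differed between P5 and P15, 4856 higher and 4891 lower, and 3233 of them by at least 2-fold (1269 higher, 1964 lower). With the batch A libraries alone the count was 9464, of which 9293 were shared. Scaling by total counts instead of trimmed means left 39.2% of the called genes higher in place of 49.8% and moved the median log2 change of all genes from -0.02 to -0.14. Folds are given relative to the trimmed-mean scale. The number of changed members differed in 11 of the 31 lists when adjusted over the list alone, by at most 3 members. With the mean level of the spectrin genes Sptan1 and Sptbn1 in each library as a further covariate, added after seeing the data, 3049 genes passed, and Pth2r, Gabra5, Slc12a2, Slc17a6, Rpl22, Fibcd1 and Reln did not. Dbn1 (-0.93) and Lpar1 (-0.50) changed sign.

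Between P5 and P28, the whole span, immature neuron genes fell while granule cell identity and postsynaptic density genes rose. Dcx reached 16.5 ± 1.24 CPM at P28 (log2 change -5.58, SE 0.10, adjusted p = 5.1e-21), Igfbpl1, another gene of newborn neurons, 2.57 ± 0.702 from 75.4 ± 18 CPM (-5.10, SE 0.17) and Crmp1 395 ± 12.3 from 1620 ± 48.5 (-2.01, SE 0.06). Slc30a3 reached 208 ± 8.51 CPM (2.32, SE 0.07), Grin2a 424 ± 11.6 (3.01, SE 0.12), Bcl6 161 ± 6.42 (2.31, SE 0.10), Camk2a 6620 ± 109 (1.89, SE 0.08) and Slc17a7 1460 ± 27.8 (1.29, SE 0.07). Slc12a5 rose by 1.25 (SE 0.06) and Gabra2 by 0.47 (SE 0.07). Those that fell were Gabra5 (-0.91, SE 0.06), Slc12a2 (-0.34, SE 0.09), Slc17a6 (-1.97, SE 0.22), Sox11 (-1.83, SE 0.10), Calb2 (-1.64, SE 0.44) and Rpl22 (-0.56, SE 0.05). Calb1 (602 ± 31.2 CPM at P28), Prox1 (515 ± 16.9), Grin2b (749 ± 35.6) and Rbp4 (8.85 ± 0.335) did not pass the test. The immature neuron list (25 of 30 lower, 3 higher) was the single list whose call held with an estimated correlation, at adjusted p = 0.0258.

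The 10 highest fold changes from P5 to P28 were those of Mobp (116 ± 20.1 CPM at P28), Mog (8.34 ± 0.517), Mal (34.3 ± 3.69), the netrin gene Ntn5 (12.7 ± 1.87, from 0.132 ± 0.116), Pla2g2f (log2 change 6.56, SE 0.26), Ptgs2 (6.55, SE 0.26), the serine protease gene Htra4 (5.52, SE 0.28), Gpnmb (5.36, SE 0.32), Anxa11 (5.04, SE 0.15) and Gsn (5.03, SE 0.49). The 10 lowest were Mgam (from 28.6 ± 7.67 to 0.127 ± 0.177 CPM), Trim67 (-6.99, SE 0.17), St8sia2 (-6.86, SE 0.25), Cenpf (-6.71, SE 0.21), Crabp1 (-6.51, SE 0.24), Draxin (-6.09, SE 0.20) and the collagen genes Col3a1 (-7.27, SE 0.54), Col1a1 (-6.63, SE 0.39), Col1a2 (-5.95, SE 0.33) and Col4a1 (-5.93, SE 0.50). The fitted collagen changes refer to the P5 libraries of batch A, which stood apart from the 2 of batch B: 213 to 298 CPM against 38.6 and 50.3 for Col3a1, 154 to 206 against 25.8 and 33.3 for Col1a1, 138 to 180 against 30.3 and 34.4 for Col1a2 and 561 to 760 against 70.5 and 153 for Col4a1. Without the batch term they were -6.69 for Col3a1, -6.03 for Col1a1, -5.39 for Col1a2 and -5.36 for Col4a1. Granule cell identity genes rose in 15 of 18 cases (adjusted p = 4.4e-14, and adjusted p = 0.177 with an estimated correlation), with Plk5 at 4.18 (SE 0.12) and Gabrd at 2.52 (SE 0.10). Postsynaptic density genes rose in 33 of 44 cases (adjusted p = 3.2e-11, and adjusted p = 0.177 with an estimated correlation), and Dlg2, Shank1, Dlgap4, Begain and Abi2 fell, the last with a change of 0.03 under the spectrin covariate. Cholesterol biosynthesis genes fell in 23 of 26 cases (adjusted p = 1.0e-09, and adjusted p = 0.177 with an estimated correlation). Of 24 interneuron genes 5 rose and 14 fell (median -1.27, adjusted p = 0.107), and of 23 CA pyramidal genes 8 rose and 13 fell (median -0.36, adjusted p = 0.66), Gad1 (1.20, SE 0.09) and Fibcd1 (0.94, SE 0.22) being among those that rose. Oligodendrocyte genes rose in 13 of 20 cases and fell in 5 (adjusted p = 0.0164, and 0.624 with an estimated correlation), a call lost with the spectrin covariate, and Mbp rose by 2.64 (SE 0.22). Endothelial and mural genes fell in 14 of 19 cases (adjusted p = 0.00055), Cajal-Retzius genes in 11 of 12 (0.00212), choroid plexus, ependymal and blood genes in 11 of 13 (0.00572), stem and progenitor genes in 17 of 20 (1.98e-06), cell cycle genes in 28 of 35 (4.77e-06) and synaptic adhesion genes in 70 of 108, with 22 higher (0.000794). Presynaptic genes rose in 43 of 63 cases and fell in 15 (adjusted p = 8.4e-06), voltage-gated channel genes rose in 44 of 75 and fell in 20 (0.00055), activity-regulated genes rose in 26 of 41 and fell in 9 (0.000602), nuclear respiratory chain genes rose in 67 of 80 (4.77e-06), heat shock genes in 15 of 18 (0.0279) and genes of GABA-A receptors and chloride transport in 12 of 21, with 8 lower (0.031, and 0.0592 without P5 replicate 1 of batch A). The last 2 calls were lost without the batch term. With an estimated correlation, no list of this comparison other than the immature neuron one kept its call. Cldn5 fell by 3.32 (SE 0.20) and Aqp4 fell by 0.93 (SE 0.14). C1qa measured 3.10 ± 0.632 and 2.03 ± 0.0998 CPM (adjusted p = 0.077).

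In total 11013 genes differed between P5 and P28, 5418 higher and 5595 lower, and 4477 by at least 2-fold. All P28 libraries were made in batch C, so age and batch cannot be separated. Those libraries also held almost no reads of the Y-linked gene Ddx3y (0 to 0.274 CPM, against 6.55 to 35.1 at P5). Sex therefore cannot be separated from age here either. The count was 4887 with the spectrin covariate, under which Slc12a2, Calb2 and Fibcd1 did not pass. Scaling by total counts moved the median log2 change of all genes from -0.01 to -0.14. In 5 of 31 lists the number of changed members differed when adjusted over the list alone, by at most 3.

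The highest changes from P5 to P7, the first interval sampled, included those of the spectrin genes Sptan1 and Sptb. Sptan1, the alpha spectrin gene on chromosome 2 from 29965560 to 30031451, went from 3760 ± 2770 CPM (n = 5) to 34700 ± 7780 (n = 3), a log2 change of 2.36 (SE 0.34, adjusted p = 0.00066). Sptb (2.21, SE 0.28), the actin crosslinker gene Actn2 (2.50, SE 0.36), Lima1 (2.53, SE 0.40), Ppp1r9a, which encodes neurabin (2.37, SE 0.40), and Gsn (2.38, SE 0.49) were the others among the 6 highest. With the spectrin covariate Lima1 (-0.37), Gsn (-0.83) and Ppp1r9a (-0.20) changed sign, as did Mgam (0.89) and Dbn1 (-0.04) below. Between libraries of an age these genes varied with Sptan1 and Sptbn1 (r = 0.971 for Lima1, 0.964 for Sptb, 0.948 for Actn2, 0.937 for Ppp1r9a and 0.935 for Gsn). The 6 lowest were Mgam (-1.62, SE 0.30), Tnxb (-1.55, SE 0.23), Tes (-1.46, SE 0.40), Cenpf (-1.46, SE 0.18), St8sia2 (-1.29, SE 0.17) and the glypican gene Gpc2 (-1.26, SE 0.26). Trp53bp1, which encodes a DNA damage response protein and was the most counted gene in each P5 library, went from 50800 ± 3320 to 25900 ± 2780 CPM (-0.97, SE 0.15); it was named after its values were seen. Immature neuron genes fell in 16 of 30 cases and Dbn1 rose (adjusted p = 1.4e-14, and 0.0267 with an estimated correlation), with Dcx at -0.88 (SE 0.09), Crmp1 at -0.47 (SE 0.06) and Sox4 at -0.87 (SE 0.13). Postsynaptic density genes rose in 28 of 44 cases (adjusted p = 1.4e-27, and 0.0267 with an estimated correlation), with Kalrn at 1.02 (SE 0.10), Shank3 at 1.01 (SE 0.12) and Icam5 at 0.51 (SE 0.06).

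**Figure D4:**
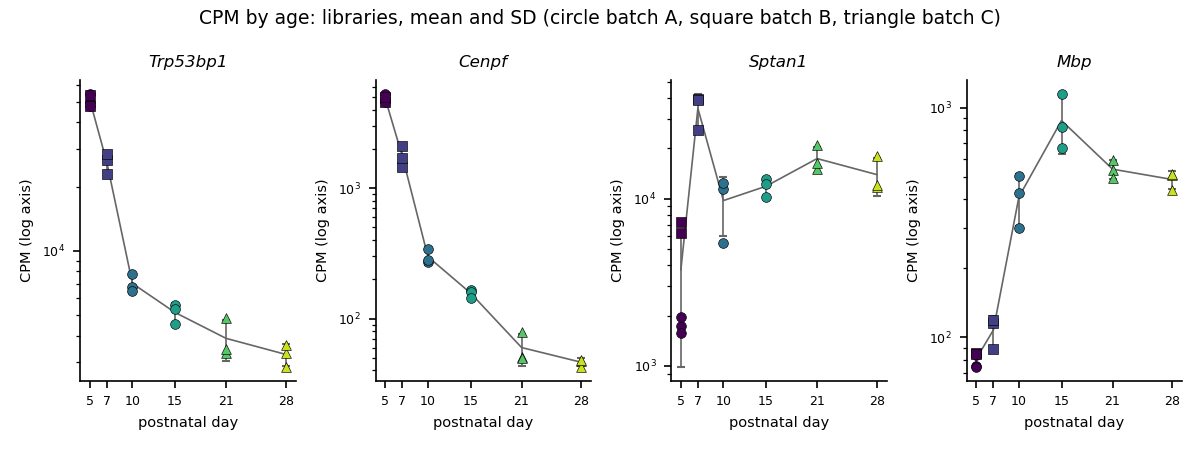
Points give the CPM of single libraries (log y axis) against postnatal day (x axis) for Trp53bp1, Cenpf, Sptan1 and Mbp, shaped by batch; lines join the age means and bars give the SD. Sptan1 stood at 1750 CPM in the P5 libraries of batch A, 6760 in those of batch B and 34700 at P7.

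Other lists also moved between P5 and P7, though their calls were lost with an estimated correlation. Axon guidance genes fell in 21 of 75 cases (adjusted p = 3.9e-07, and adjusted p = 0.0985 with an estimated correlation), with Neo1 at -0.58 (SE 0.07) and Draxin at -1.18 (SE 0.14), and Robo3 and Slit1 rose. Ribosomal protein genes fell in 25 of 82 cases (adjusted p = 2.2e-11, and adjusted p = 0.471 with an estimated correlation). Synaptic adhesion genes fell in 21 of 108 (adjusted p = 2.5e-07, and adjusted p = 0.465 with an estimated correlation), with C1ql2, Gpr158 and Cntnap1 higher. Presynaptic genes rose in 16 of 63 cases (adjusted p = 0.000434, and adjusted p = 0.527 with an estimated correlation), with Vamp1 at 0.73 (SE 0.11) and Syt7 at 0.38 (SE 0.06). Unc13b fell by 0.72 (SE 0.11). Granule cell identity genes rose in 7 of 18 cases (adjusted p = 0.000784, and adjusted p = 0.527 with an estimated correlation), with Lct at 0.94 (SE 0.14) and Slc30a3 at 0.44 (SE 0.08). Without P7 replicate 1 this call was lost (adjusted p = 0.106). Astrocyte genes rose in 6 of 19 cases (adjusted p = 1.6e-05, and adjusted p = 0.465 with an estimated correlation): Gfap, Aqp4, Slc1a2, Gjb6, S100b and Ntsr2, while Fabp7 fell by 0.60 (SE 0.11). With the spectrin covariate the median of the astrocyte list was -0.31, and Gfap (-0.25), Aqp4 (-0.06), Slc1a2 (-0.37), Gjb6 (-0.36) and S100b (-0.31) changed sign. Oligodendrocyte genes lay higher as a list, with 0 members past the threshold (median 0.57, adjusted p = 0.000548, and adjusted p = 0.527 with an estimated correlation). This call was lost without the batch term, and the median was -0.32 with the spectrin covariate. Voltage-gated channel genes rose in 13 of 75 cases and fell in 1 (adjusted p = 0.0061, and 0.471 with an estimated correlation) and activity-regulated genes in 10 of 41 (0.0015, and 0.465), while cholesterol biosynthesis genes fell in 6 of 26 (5.27e-05, and 0.465). These 3 calls were lost with the spectrin covariate.

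In total 1698 genes differed between P5 and P7, 946 higher and 752 lower, and 136 of them by at least 2-fold (115 higher, 21 lower). Within batch B, which holds 2 P5 libraries and all 3 of P7, the count was 621, of which 583 were shared, and Gsn, Tnxb and Gpc2 did not pass. The count was 518 without P5 replicate 1 of batch B and 1020 without P5 replicate 3 of batch B. Gsn was lost without the latter, Gpc2 without the former, and Tes without either of them and without P7 replicate 1 or 3. With the spectrin covariate 0 genes passed in edgeR (675 had an unadjusted p under 0.05) and 0 in limma-voom (734). Without a batch term 3586 genes passed. Scaling by total counts gave 3035, of which 18% were higher in place of 55.7%, with the median of all genes at -0.10 in place of 0.01. Adjusted over the list alone, the number of changed members differed in 18 of 31 lists, by up to 12 for the ribosomal proteins.

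The interval from P7 to P10, which crosses from batch B to batch A, held the largest number of changes between neighboring ages. The 2 steps that cross batches gave 6578 (P7 to P10) and 4421 genes (P15 to P21). Steps that can be compared inside a batch gave 1698 (P5 to P7), 670 (P10 to P15) and 39 (P21 to P28). The ranking of steps thus follows the batches and is not read as a ranking of change with age. Dcx went from 358 ± 55.5 CPM to 99.1 ± 7.14 (n = 3 each), Grin2a from 106 ± 21.6 to 281 ± 17.8 and Slc30a3 from 71.2 ± 9.04 to 149 ± 6.63. Because P7 and P10 were in different batches, the fitted changes carry the batch B term and are larger than the ratio of these means for many genes: -2.12 (SE 0.12) for Dcx, 1.85 (SE 0.17) for Grin2a and 1.40 (SE 0.11) for Slc30a3 (adjusted p = 1.3e-10, 2.2e-07 and 1.9e-09). Respiratory chain genes rose in 75 of 80 cases and Cox6b2 fell (adjusted p = 2.3e-21, and adjusted p = 0.152 with an estimated correlation), with Cox8a at 0.92 (SE 0.10) and Cox6a1 at 0.62 (SE 0.07). The fall of Cox6b2 was lost without any 1 of P5 replicates 1 and 3 of batch A, P5 replicate 1 of batch B, P7 replicates 2 and 3 and P10 replicates 1 and 2 (adjusted p from 0.053 to 0.177). Presynaptic genes rose in 40 of 63 cases, postsynaptic density genes in 28 of 44 and granule cell identity genes in 14 of 18 (adjusted p = 5.0e-12 for each, and adjusted p = 0.118 for each with an estimated correlation), among them Snap25 (1.02, SE 0.09), Ppp3r1 (1.37, SE 0.10) and Lct (2.50, SE 0.19). Cell cycle genes fell in 27 of 35 cases (adjusted p = 3.4e-09), stem and progenitor genes in 15 of 20 (adjusted p = 6.5e-10) and immature neuron genes in 14 of 30 (adjusted p = 2.1e-06), each with adjusted p = 0.118 with an estimated correlation, among them Top2a (-2.41, SE 0.32), Vim (-2.59, SE 0.16) and Sox11 (-1.45, SE 0.14). Endothelial and mural genes fell in 11 of 19 cases (adjusted p = 6.9e-05, and adjusted p = 0.19 with an estimated correlation), and Cdh5 fell by 2.38 (SE 0.37). Cajal-Retzius genes fell in 11 of 12 cases and Car10 rose (median -1.54, adjusted p = 0.000346, and adjusted p = 0.118 with an estimated correlation). Astrocyte genes fell in 9 of 19 cases and rose in 3 (median -0.67, adjusted p = 0.000912, and adjusted p = 0.327 with an estimated correlation), and choroid plexus, ependymal and blood genes fell in 5 of 13 (median -1.30, adjusted p = 0.00314, and adjusted p = 0.269 with an estimated correlation). Voltage-gated channel genes rose in 38 of 75 cases and fell in 9 (adjusted p = 3.87e-06), activity-regulated genes rose in 22 of 41 and fell in 3 (2.55e-05), genes of GABA-A receptors and chloride transport rose in 13 of 21 (2.21e-05) and cholesterol biosynthesis genes fell in 12 of 26 and rose in 1 (0.0011). With an estimated correlation the adjusted p was 0.118 for the first 3 of these lists and 0.312 for the last. Heat shock genes rose in 8 of 18 cases and fell in 1 (adjusted p = 0.0319, and 0.0574 without P5 replicate 1 of batch B), and neuronal transcription factor genes rose in 35 of 112 and fell in 23 (0.0204, and 0.07 without P5 replicate 3 of batch B). Both of these calls were lost with an estimated correlation (adjusted p = 0.269 for each).

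The 6 highest changes from P7 to P10 were those of Tnnt2 (log2 change 4.14, SE 0.55, and 2.26 without the batch term), Ptgs2 (3.67, SE 0.54), the peptide receptor gene Glp2r (3.35, SE 0.25), the complexin gene Cplx3 (3.11, SE 0.90), Krt9 (2.95, SE 0.32) and Mag (2.89, SE 0.78). Without the batch term these were 2.30 for Ptgs2, 1.77 for Glp2r, 1.86 for Cplx3, 1.95 for Krt9 and 3.12 for Mag. Cplx3 was lost without P5 replicate 3 of batch B (1.90, adjusted p = 0.178), which held 4.69 CPM of it against 1.04 to 1.5 in the other P5 libraries. Mag was lost without P5 replicate 1 of batch B (adjusted p = 0.0557). The 6 lowest were Crabp1 (-4.20, SE 0.28) and the collagen genes Col4a5 (-4.23, SE 0.57), Col3a1 (-4.20, SE 0.56), Col4a1 (-3.90, SE 0.61), Col1a2 (-3.79, SE 0.37) and Col1a1 (-3.79, SE 0.42). Without the batch term Crabp1 was at -3.28 and Col1a2 at -1.49, and Col4a5 (-1.61), Col3a1 (-1.70), Col4a1 (-1.41) and Col1a1 (-1.14) did not pass. In total 6578 genes differed, 3455 higher and 3123 lower, with 434 higher and 1542 lower by at least 2-fold. The ages were joined only through the P5 libraries of both batches, and no list call held with an estimated correlation (the lowest adjusted p was 0.118). Adjusted over the list alone, the number of changed members differed in 17 of 31 lists, by up to 8 for the ribosomal proteins.

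From P10 to P15, within batch A, myelin genes rose and immature neuron genes fell. Mobp went from 51.4 ± 20.7 to 159 ± 50.3 CPM (n = 3 each), a log2 change of 1.63 (SE 0.28, adjusted p = 0.0073), and Mal (2.01, SE 0.30) and Mag (1.25, SE 0.24) rose as well. Npas4, a transcription factor gene induced by neuronal activity, rose from 4.46 ± 0.418 to 13.5 ± 0.826 CPM (1.60, SE 0.28), and the cytochrome P450 gene Cyp2d22 (1.29, SE 0.33) was also among the 6 highest. The 6 lowest were Dpysl3, a collapsin response mediator gene (-1.29, SE 0.18), Rasgrp2 (-1.20, SE 0.27), Palm3 (-1.17, SE 0.19), Trim67 (-1.08, SE 0.14), the adhesion gene Cxadr (-1.03, SE 0.16) and Cpne5 (from 27.3 ± 10.2 to 13.6 ± 1.71 CPM). Immature neuron genes fell in 12 of 30 cases (adjusted p = 1.5e-16, and 0.0292 with an estimated correlation), with Dcx at -0.68 (SE 0.09). Activity-regulated genes rose in 12 of 41 cases (adjusted p = 3.2e-09, and adjusted p = 0.0949 with an estimated correlation), with Gadd45g at 0.71 (SE 0.10), Btg2 at 0.67 (SE 0.11) and Arl4d at 0.92 (SE 0.15). Oligodendrocyte genes rose in 11 of 20 cases and none fell (adjusted p = 3.3e-20, and adjusted p = 0.1 with an estimated correlation). Astrocyte genes (median 0.28, adjusted p = 0.000574, and 0.723 with an estimated correlation) and microglial genes (0.35, 0.0152, and 0.735) lay higher as lists, with 0 members up past the threshold. Without P10 replicate 3 both calls were lost (adjusted p = 0.122 and 0.199), and without P15 replicate 3 the microglial one was (adjusted p = 0.218). Synaptic adhesion genes fell in 14 of 108 cases (adjusted p = 1.73e-10, and 0.207 with an estimated correlation), axon guidance genes in 10 of 75 (2.01e-06, and 0.117) and cholesterol biosynthesis genes in 5 of 26 (6.39e-07, and 0.285), and granule cell identity genes rose in 4 of 18 (0.000201, and 0.723).

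Other list calls from P10 to P15 depended on single libraries, and none held with an estimated correlation (adjusted p of 0.735 to 0.841). Presynaptic genes lay lower (median -0.09, adjusted p = 0.0122) and were lost without P10 replicate 3 (0.0561) or P15 replicate 3 (0.0828). Postsynaptic density genes lay higher (median 0.07, adjusted p = 0.0136) and were lost without P10 replicate 3 (0.118) or P15 replicate 1 (0.0508). Imprinted genes lay lower (median -0.16, adjusted p = 0.0179) and were lost without P10 replicate 1 (0.11) or P10 replicate 3 (0.122). Nuclear respiratory chain genes lay lower (median -0.05, adjusted p = 0.0137) and were lost without P10 replicate 2 (0.0522), P10 replicate 3 (0.0561) or P15 replicate 3 (0.448).

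In total 670 genes differed between P10 and P15, 283 higher and 387 lower, with 36 higher and 21 lower by at least 2-fold. This count depended on single libraries: it was 209 without P10 replicate 1, 1473 without P10 replicate 2, 108 without P10 replicate 3, 243 without P15 replicate 2 and 127 without P15 replicate 3. P10 replicate 3 held 0.925% of its counts in Sptan1 and Sptbn1 against 1.82% and 1.95% in the other P10 libraries, and P15 replicate 3 had the highest Mbp level of its age. Without both, a setting added after seeing the data, 21 genes passed. Dcx, Trim67, Gadd45g, Btg2 and Arl4d were still past the threshold, while Npas4, Dpysl3, Mobp, Mag, Cyp2d22, Rasgrp2, Palm3, Cxadr and Cpne5 were not. Cyp2d22, Rasgrp2 and Cpne5 were each lost without any of P10 replicate 1, P10 replicate 3, P15 replicate 2 and P15 replicate 3. Mag was lost without the first 2 of these or the last, and Cpne5 also without P15 replicate 1. Adjusted over the list alone, the number of changed members differed in 19 of 31 lists, by up to 11 for axon guidance.

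Between P15 and P21 granule cell identity genes rose, and immature neuron, activity-regulated and interneuron genes fell. Plk5, a granule cell identity gene, went from 12.4 ± 1.21 to 39.9 ± 4.85 CPM (n = 3 each), a log2 change of 1.69 (SE 0.10, adjusted p = 3.5e-11). In all, 12 of the 18 identity genes rose (adjusted p = 1.6e-08, and adjusted p = 0.3 with an estimated correlation). The other 5 of the 6 highest were Bc1, a short neuronal noncoding RNA (2.68, SE 0.34), Ntn5 (2.61, SE 0.23), the proenkephalin gene Penk (2.16, SE 0.29), the follistatin gene Fst (2.05, SE 0.21) and the long noncoding RNA Neat1 (1.72, SE 0.32). The 6 lowest were the imprinted genes Mkrn3 (-2.91, SE 0.18) and Rian (-2.73, SE 0.27), the collagen genes Col1a1 (-2.27, SE 0.39) and Col3a1 (-2.20, SE 0.58), Trim67 (-2.22, SE 0.18) and the orexin receptor gene Hcrtr1 (-2.17, SE 0.24). Immature neuron genes fell in 16 of 30 cases (adjusted p = 7.0e-11, and adjusted p = 0.0978 with an estimated correlation), with Dcx at -1.67 (SE 0.09) and Igfbpl1 at -1.77 (SE 0.17). Neurod2 and Prdm8 rose. Activity-regulated genes fell in 25 of 41 cases (adjusted p = 0.000225, and adjusted p = 0.256 with an estimated correlation), including Egr4 (-0.76, SE 0.10) and Pcsk1 (-0.89, SE 0.12). Jun, Penk, Inhba, Scg2, Ptgs2 and Mapk4 rose. Interneuron genes fell in 13 of 24 cases (adjusted p = 5.5e-05, and adjusted p = 0.235 with an estimated correlation), with Lhx6 at -1.29 (SE 0.17), Tac1 at -1.97 (SE 0.27) and Npy at -1.04 (SE 0.15). Gad1 and Nos1 rose. CA pyramidal genes fell in 8 of 23 cases and Rgs14 rose (median -0.42, adjusted p = 0.00365, and adjusted p = 0.0978 with an estimated correlation). Endothelial and mural genes fell in 7 of 19 cases and Slco1a4 rose (median -0.56, adjusted p = 0.0169, and adjusted p = 0.673 with an estimated correlation), a list call lost without P15 replicate 3 (adjusted p = 0.0561) or P21 replicate 2 (adjusted p = 0.0512). Slco1a4 was lost without P15 replicate 1 (0.65, adjusted p = 0.0772) or P21 replicate 3 (0.72, adjusted p = 0.071) and with the spectrin covariate, and Rgs14 without the batch term. Cholesterol biosynthesis genes fell in 13 of 26 cases (adjusted p = 2.8e-07, and adjusted p = 0.256 with an estimated correlation). Axon guidance genes fell in 32 of 75 cases and rose in 8 (adjusted p = 0.000185, and 0.256 with an estimated correlation). Nuclear respiratory chain genes fell in 18 of 80 and rose in 2 (0.0296, and 0.777), a call lost without P15 replicate 1 (0.18), P15 replicate 2 (0.0555) or P21 replicate 3 (0.166). Heat shock genes rose in 4 of 18 (0.0178, and 0.325), a call lost without P15 replicate 3 (0.0561). The postsynaptic scaffold genes Shank3 (-1.30, SE 0.11) and Shank1 (-1.09, SE 0.10) fell, while the list as a whole did not pass (5 higher and 13 lower of 44, adjusted p = 0.181).

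In total 4421 genes differed between P15 and P21, 2150 higher and 2271 lower, with 127 higher and 399 lower by at least 2-fold. The 2 ages lay in different batches with no shared age, so age and batch cannot be told apart here, and no list call held with an estimated correlation (the lowest adjusted p was 0.0978). Col1a1 and Col3a1 did not pass without the batch term. Adjusted over the list alone, the number of changed members differed in 17 of 31 lists, by up to 6 for cholesterol biosynthesis.

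Few genes differed between P21 and P28, both in batch C. Gpc3, a glypican gene, went from 5.64 ± 0.242 to 10.7 ± 0.264 CPM (n = 3 each), a log2 change of 0.93 (SE 0.12, adjusted p = 0.00062). The retinol transporter gene Stra6 rose by 0.86 (SE 0.13) and Plk5 by 0.76 (SE 0.09). The other 3 of the 6 highest were Csgalnact1 (0.57, SE 0.12), Smad1 (0.43, SE 0.08) and Bhlhe40 (0.37, SE 0.08). Hemoglobin genes fell, Hbb-bs from 10.2 ± 4.08 to 2.79 ± 0.193 CPM (-1.86, SE 0.26), Hba-a1 (-1.66, SE 0.24) and Hba-a2 (-1.64, SE 0.32). These are near-identical copies whose counts are uncertain. Glp2r (-0.76, SE 0.11), Fgd6 (-0.90, SE 0.19) and Slc9a3r1 (-0.71, SE 0.15) were the others among the 6 lowest. Astrocyte genes lay lower as a list (median -0.47, adjusted p = 1.4e-13, and adjusted p = 0.179 with an estimated correlation), Slc4a4 (-0.51, SE 0.09) being the member past the threshold. The other lists of non-neuronal cells lay lower too: choroid plexus, ependymal and blood (median -0.44, adjusted p = 2.65e-10), stem and progenitor (-0.40, 6.08e-08), endothelial and mural (-0.45, 0.00192), microglial (-0.33, 0.00267) and oligodendrocyte (-0.24, 0.00291). With an estimated correlation their adjusted p were 0.138, 0.179, 0.515, 0.589 and 0.589, and the last 2 lists were lost without P28 replicate 2 (adjusted p = 0.11 and 0.107) and with the spectrin covariate. Ribosomal protein genes lay higher (median 0.13, adjusted p = 1.6e-20, and adjusted p = 0.404 with an estimated correlation). Cell cycle (median -0.22, adjusted p = 0.0302), glutamate receptor (-0.05, 0.0403), postsynaptic density (-0.03, 0.00569) and mitochondrially encoded genes (-0.21, 0.0456) lay lower, none with an estimated correlation (0.515 to 0.589). The first was lost without P21 replicate 1 (0.0928) and the third without P28 replicate 1 (0.056). The second was lost without P21 replicate 2 (0.0611), P21 replicate 3 (0.114), P28 replicate 2 (0.0629) or P28 replicate 3 (0.12), and the fourth without P21 replicate 2 (0.258) or P28 replicate 2 (0.381). When adjusted over the list alone, 11 astrocyte genes were lower and 19 ribosomal protein genes higher.

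In total 39 genes differed between P21 and P28, 10 higher and 29 lower, 6 of them lower by at least 2-fold. The Y-linked gene Ddx3y stood at 0.298, 29.4 and 25.8 CPM in the P21 libraries and at 0 to 0.274 at P28. The 2 ages thus differed in the sex of the animals as well. Scaling by total counts left 51.5% of 33 called genes higher in place of 25.6%. The count was 20 without P21 replicate 2, 12 without P21 replicate 3, 14 without P28 replicate 1, 9 without P28 replicate 2 and 14 without P28 replicate 3. Gpc3, Stra6, Plk5 and Hbb-bs passed without any 1 library, as did Glp2r and Hba-a1, though the last 2 did not pass without the batch term. Smad1 was lost without P21 replicate 2 or 3 or P28 replicate 2. Hba-a2 and Slc9a3r1 were lost without P21 replicate 1 or 3 or any P28 library, Bhlhe40 without P21 replicate 2 or 3 or any P28 library. Csgalnact1 and Fgd6 were lost without any of the 6 libraries, and Slc4a4 was lost without P21 replicate 3 or P28 replicate 2. With the 6 libraries of these ages alone 277 genes passed, and DESeq2 called 165. Adjusted over the list alone, the number of changed members differed in 17 of 31 lists.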

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

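No test of this part was chosen only after the result was seen. Only P5, with 5 libraries, was large enough to look for a library that stands apart, and 226 results were tested (CPM at P5 of each tested gene the text names, the total count and the first component). In 5 of them the gap between the most extreme library and its nearest neighbor exceeded the 95% bound as a share of the whole range, where chance gives about 1 in 20, or 11.

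The oligodendrocyte gene Mag stood at 1.15 CPM in P5 replicate 1 of batch A and at 0.405 to 0.573 in the other 4 libraries (share 0.774). The same library held the lowest value of Kl (7.71 CPM against 9.32 to 9.84, share 0.754) and the highest of mt-Nd6 (2.01 against 0.621 to 0.99, share 0.735). P5 replicate 3 of batch B held the highest value of the complexin gene Cplx3 (4.69 CPM against 1.04 to 1.5, share 0.872) and of the enkephalin gene Penk (4.59 against 2.95 to 3.03, share 0.953).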

How the results depend on the processing

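The spectrin covariate, the setting without P10 replicate 3 and P15 replicate 3 and the list tests under these and under total counts were chosen only after the result was seen. The covariate is the mean log2 CPM of Sptan1 and Sptbn1 per library, which itself differs between ages, so it can take up changes with age as well.

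At least 2-fold in addition to the threshold left 5310 genes over all ages, 136 from P5 to P7, 1976 from P7 to P10, 57 from P10 to P15, 526 from P15 to P21, 6 from P21 to P28, 3233 from P5 to P15, 4477 from P5 to P28 and 89 for batch B. An adjusted p of 0.01 left 769 from P5 to P7, 170 from P10 to P15, 2721 from P15 to P21, 11 from P21 to P28 and 736 for batch B. Among genes with a range of at least 4-fold the highest mean lay at P5 for 956, P7 for 613, P10 for 71, P15 for 71, P21 for 230 and P28 for 294.

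From P5 to P7 the count was 3035 with total counts, 3586 with no batch term, 4573 with the P5 libraries of batch B left out, 3571 with P5 libraries of the same number summed, 621 in batch B alone and 0 with the spectrin covariate. With those P5 libraries left out or summed, the batch term cannot be estimated. The counts of 4573 and 3571 therefore do not separate age from batch B. From P10 to P15 it was 1007 in DESeq2, 405 with no batch term, 263 with the spectrin covariate, 21 without P10 replicate 3 and P15 replicate 3 and 210 with the libraries of the 2 ages alone. From P21 to P28 it was 64 with no filter, 165 in DESeq2, 17 in limma-voom, 11 with no batch term, 13 with the spectrin covariate and 277 with the libraries of the 2 ages alone. With the spectrin covariate it was 3049 from P5 to P15, 4887 from P5 to P28 and 12 for batch B, and with the P5 and P7 libraries alone it was 894 for batch B. The replicate number as a block gave 19 genes from P21 to P28 and counts within 1.5 times the others elsewhere. Libraries of the same number at different ages did not vary together (18 of 55 pairs with r above 0.1, from -0.507 to 0.382). The number thus does not pair samples between ages. These pairs do not cover the same-numbered libraries of the 2 P5 series. For those, the difference between replicates 1 and 3 correlated at -0.303 between the series. Whether they share an animal or lysate is not given by the labels and stays open.

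Leaving out 1 library at a time gave 11615 to 12344 genes over all ages, 518 to 1654 from P5 to P7, 4896 to 6745 from P7 to P10, 108 to 1473 from P10 to P15, 3400 to 3801 from P15 to P21, 9 to 28 from P21 to P28, 9017 to 9707 from P5 to P15, 10343 to 10971 from P5 to P28 and 613 to 1848 for batch B.

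From P7 to P10 the sign reversed for Hsp90ab1 (-0.15), mt-Co1 (0.01) and mt-Nd1 (0.26) with no batch term. It also reversed with the P5 libraries of batch B left out (-0.16, 0.01 and 0.26) and with those of the same number summed (-0.16, 0.01 and 0.26). The libraries of the 2 ages alone gave -0.16, 0.01 and 0.25. The batch term cannot be estimated in these settings either, so they are not separate checks. With the P5 libraries of batch B left out, Atp5mpl reversed from P5 to P7 (0.07). With the spectrin covariate these reversed from P5 to P7: Lima1 (-0.37), Gsn (-0.83), Ppp1r9a (-0.20), Mgam (0.89), Gjb6 (-0.36), S100b (-0.31), Slc1a2 (-0.37), Smarca4 (-0.03), Gad2 (-0.10), Atp5mpl (0.03), Aqp4 (-0.06), Dbn1 (-0.04), Gfap (-0.25) and the medians of the oligodendrocyte (-0.32) and astrocyte (-0.31) lists. With it, Dbn1 (-0.93), Lpar1 (-0.50) and Sptbn1 (-0.26) reversed from P5 to P15 and Abi2 (0.03) from P5 to P28. Sptbn1 is itself part of the covariate, so its reversal is no test of its change.

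Gene results fell below the threshold with the same sign in 182 cases with the spectrin covariate, 81 without P10 replicate 3 and P15 replicate 3, 65 with the libraries of the 2 ages alone, 57 with no batch term, 35 in batch B alone, 32 in limma-voom, 26 with the block, 23 with summed libraries, 21 with total counts, 16 with no filter, 12 with the P5 libraries of batch B left out, 3 in DESeq2, 3 with DESeq2 size factors, 2 with the stricter filter, 0 in batch A alone and 442 over all libraries left out in turn. The settings covered unlike numbers of gene results, so these counts cannot be compared directly. The call stayed the same for 59 results in batch B alone, 178 in batch A alone, 757 in limma-voom and 5799 over libraries left out in turn. Of 217 list results per setting, 96 fell below it with an estimated correlation, 24 with fry, 12 with the spectrin covariate, 7 without P10 replicate 3 and P15 replicate 3, 6 with no batch term and 1 with total counts, while 29 passed it only with fry, 15 only with the spectrin covariate, 11 only with no batch term and 7 only with total counts.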

Other observations

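Of the tests below, those on the tag core class, the spectrin genes with the protein families and the oligodendrocyte genes, as well as the spectrin covariate, were chosen only after the result was seen, as were the bounds of the class and family tests. The search for the tag in the Trp53bp1 protein was set after the counts of this gene but before any protein match was seen, and the splits of the samples were set before their results, except that those within batches were chosen after them.

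Regulators of transcription and RNA processing changed in both directions from P5 to P15. Of 112 neuronal transcription factors 41 rose and 40 fell (adjusted p = 0.0617), and those with the smallest p all rose: the circadian factor gene Tef (log2 change 1.86, SE 0.06), the glucocorticoid-responsive gene Klf9 (2.25, SE 0.08), Elk1 (1.58, SE 0.07) and Bhlhe41 (2.44, SE 0.11). Of 42 genes of RNA-binding and splicing proteins 17 rose and 19 fell (median -0.11, though the list test pointed up, adjusted p = 0.689), with Cpeb1, a regulator of poly-A tail length, at 2.47 (SE 0.11), the splicing factor genes Rbfox1 at 1.70 (SE 0.08) and Rbfox3 at 0.86 (SE 0.05) and Celf1 at 0.87 (SE 0.06). Of 56 chromatin regulators 14 rose and 20 fell (adjusted p = 0.578), with Hmgb3 at -1.73 (SE 0.12), the linker histone gene H1f0 at 0.71 (SE 0.05) and the Polycomb methyltransferase gene Ezh1 at 0.82 (SE 0.07). Ezh1 did not pass with the spectrin covariate.

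Of 39 imprinted genes 21 fell and 7 rose from P5 to P15 (adjusted p = 0.13), with Zim1 at -2.14 (SE 0.15), Usp29 at -0.80 (SE 0.07), Impact at 1.61 (SE 0.10) and Rasgrf1, an exchange factor gene, at 2.52 (SE 0.09). Heat shock and stress genes rose in 11 of 18 cases (adjusted p = 0.23), among them the chaperone gene Hsph1 (0.45, SE 0.07). Of the 7 mitochondrially encoded genes tested, out of 13, mt-Nd2, mt-Nd5 and mt-Nd6 rose and mt-Nd1 and mt-Co1 fell (median -0.27, mean 0.31, adjusted p = 0.855). None of 5 sex-linked genes passed in edgeR from P5 to P15 (adjusted p = 0.546 for the list), while from P5 to P28 the Y-linked genes Ddx3y (-7.99), Eif2s3y (-6.73), Kdm5d (-6.90) and Uty (-5.54) fell (adjusted p = 0.476 for the list). Ddx3y, Kdm5d and Uty were lost without any 1 of P28 replicates 1, 2 and 3 (adjusted p from 0.0542 to 0.0893), Uty also without P5 replicate 3 of batch A (adjusted p = 0.0718), and all 4 in limma-voom and with the spectrin covariate. From P21 to P28 none passed, though the list did (median -5.48, adjusted p = 0.000992, and adjusted p = 0.213 with an estimated correlation). The Y-linked gene Ddx3y lay between 0 and 0.301 CPM in P10 replicate 1, P15 replicates 2 and 3, P21 replicate 1 and all P28 libraries, and between 6.55 and 55 CPM in the others. Xist, expressed from the inactive X chromosome, stood at 0.0602 CPM in P10 replicate 3, 6.87 in P10 replicate 2 and 7.59 in P7 replicate 2, and between 50.9 and 323 CPM elsewhere. Every P5 library held both Xist and Ddx3y, while no P28 library held more than 0.274 CPM of Ddx3y. The fall of the Y-linked genes to P28 therefore cannot be told apart from the sex of the animals and is not read as a change with age.

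Trp53bp1, on the minus strand of chromosome 2 from 121193281 to 121271407, took 4.81 to 5.95% of all counts in the P5 libraries, 2.11 to 2.79% at P7 and 0.284 to 0.356% at P28, and Bcar1 went from 11200 ± 1070 CPM (SD, n = 5) at P5 to 2240 ± 262 (n = 3) at P28. Capture of ribosomes through a nascent protein that resembles the HA tag was weighed as a technical explanation. The best stretch in the Trp53bp1 protein had 4 of the 9 residues of the tag in place (41.7% of proteins of similar length had fewer) and that in Bcar1 had 5 (97.4%). A value of 5 or fewer in either was set beforehand to count against it, and both met that bound. The bound counts residues in place and not runs of them, and the Trp53bp1 stretch, VPYDVNQEH, holds the run PYDV of the tag. Bcar1 lies above the 95% bound, and the related Efs had 5 (98.7%) and Nedd9 4 (67.6%). The values argue against resemblance over the whole tag for Trp53bp1 alone and leave capture through a shorter run undecided. The core YDVP or PYDV was picked after 18 stretches of the tag were scanned against levels and changes, and without the 13 genes on view then the 63 others that hold it had a median correlation of 0.034 with Trp53bp1 within ages (random sets -0.039, percentile 92.1), against 0.067 and percentile 98.7 with them, so the test decides nothing; capture of this class stays open, since Bcar1 holds 7 cores and Efs 4 and both varied with Trp53bp1 (r = 0.904 and 0.852), as did Cenpf (0.939) and Lama4 (0.913), which hold 0. A change with age itself stays open as well and was not tested.

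The spectrin genes Sptan1 and Sptbn1 together took 0.387 to 0.482% of counts in the P5 libraries of batch A, 1.44 to 1.64% in those of batch B, 5.06 to 6.48% at P7 and 0.925, 1.82 and 1.95% at P10. Batch B as the whole cause is argued against by the P7 libraries of that batch, the lowest of which lay 1.66 (log2) above its highest P5 library. Uneven recovery of long messages stays open, since 377 genes with proteins of over 2000 residues had a median correlation of 0.151 with the spectrin genes within ages. Uneven recovery of ribosomes held in actin and spectrin complexes stays open: the myosin, actinin, filamin, tropomyosin and ankyrin families were picked after 11 members were read among covarying genes, and the other 35 had a median correlation of 0.104 (random sets 0.014, percentile 92), against 0.39 and percentile 100 with them, so the test decides nothing. A change with age stays open and was not tested apart from recovery.

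Oligodendrocyte genes rose from P5 to P15 and differed between libraries of an age: Mbp stood at 299, 423 and 505 CPM in the P10 libraries and at 664, 821 and 1150 at P15. A lower share of granule cell RNA in the pull-down would raise genes of other cells. The endothelial and mural genes, a fall of which was set to count against it, had a median log2 change of -1.23. No unselected hippocampal RNA was analysed, so a fall of these genes in the tissue itself could hide a lower share. The test therefore cannot decide, and a lower share stays open. RNA of oligodendrocytes carried into the pull-down to a different degree per library stays a hypothesis, although the antibody should leave it behind. The 20 genes, of which 0 are in another list, had a median pairwise correlation of 0.611 within ages, at percentile 100 of matched random sets. Other lists varied together as much. The correlation that camera estimated from P10 to P15 was 0.576 for oligodendrocyte genes, 0.587 for granule cell identity genes and 0.503 for ribosomal protein genes. The percentile therefore cannot tell carried-over RNA from other sources of shared variation. More oligodendrocytes in the older hippocampus would raise these oligodendrocyte genes as well and was not tested.

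Other splits of the same samples into groups of the same sizes were fitted in the same way. The 12254 genes that differed over the 6 ages were reached by 1 of 100 splits, the real one, the highest other giving 3. Among 100 splits that exchanged libraries inside batches alone it was again 1, a share under 0.05. The highest others gave 11124 and 11113, as differences between the batches stay in such splits. A count near the real one can thus arise without the real ages inside batches.

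The 1698 genes from P5 to P7 were reached by 1 of 55 splits (highest other 728; 1 more could not be fitted), and the 9747 from P5 to P15 and 11013 from P5 to P28 by 2 of 56 splits each. The other one of these 2 sets the 3 P5 libraries of batch A apart and gives the same model through the batch term, and the next highest gave 0. These splits exchange libraries between batches. Inside batches there are 10 splits from P5 to P7 (real 1698, highest other 728) and 10 from P5 to P15 (9747 and 0), too few for a share under 0.05, and none from P5 to P28. Within batch A alone the count from P5 to P15 was 9464. For the remaining steps 3 libraries against 3 allow 10 splits, too few as well: the real values were 6578 from P7 to P10 (highest other 4), 670 from P10 to P15 (52), 4421 from P15 to P21 (0) and 39 from P21 to P28 (2).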
